A study of Rattus norvegicus with 6 samples.

How the data were processed

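RNA of rat H9c2 cells, 3 control and 3 H/R samples, was measured on Arraystar lncRNA and mRNA arrays made by Agilent and read in 1 colour (Cy3). Per the labels' protocols, ribosomal RNA was removed and random primers were used to make labelled cRNA over whole transcripts. The series' type also names sequencing, but the files analysed here are array files. The protocol text names a mouse brain cortex as the RNA source, which conflicts with the rat heart line in every other label; samples are described here by the latter.

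The deposited scanner files hold intensity values per spot, and per the file headers and the submitters' processing notes the authors extracted them with Agilent Feature Extraction 11.0.1.1. The processed intensity in these files is, per the file headers, corrected for background and spatial trend within the array and not normalized between arrays. Flags in the deposited files (coded 0 or 1, a kind of value other than a measurement) mark outlier, saturated and well-above-background spots. The authors also deposited a table of log2 values for 16841 probes. Its columns correlated with the log2 of the scanner values, across probes, at r of 0.9998 to 0.9999, and their medians lay between 9.182 and 9.187, so its scale is log2, genes were not centred, and the normalization method is not given in the sources used here. No direction is involved in 1-colour values.

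All fits were made with limma 3.58.1 in R 4.3.3, and files were read with Python 3.11.15 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Control spots and outlier spots were left out, spots of a probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. Each file lists 43553 spots, 42136 of them non-control. The 75th percentile of the processed signal was 1302, 1079 and 1076 units in control replicates 1 to 3 and 955.7, 1382 and 1431 in H/R replicates 1 to 3. Of 24684 probes 24578 had a usable spot in every file, and 15899 were tested because they were well above background in all 3 scans of at least 1 group. Where a probe or gene was not well above background in any scan of a group, only a bound of its fold is given. Where its own signals set that bound, the fitted fold is given and named as such.

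The groups come from the labels. The design fixed before the data were examined compared 3 with 3 samples. Because replicates 2 and 3 of each group looked like 2 scans of 1 array, they were averaged (avearrays) and the comparison became 2 arrays with 2, with 2 residual and 2.86 prior degrees of freedom; the fit of 6 scans as separate samples is given as an alternative chosen after seeing the data. All arrays lay on 1 slide, each at a position of its own, so position and group cannot be told apart. The first scan held control and H/R replicates 1 and 2 and the second held replicate 3 of both groups. The group difference was tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. On simulated data for 15899 probes with 200 changed, this fit recovered 22% of changes of 0.5 on the log2 scale, 90% of changes of 1, 98% of changes of 2 and 100% of changes of 3, and 14 of its 169 calls were unchanged probes. With the 6 scans as separate samples 422 of 611 calls were unchanged probes. These shares hold for 200 changed probes and are not estimates for the real calls.

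Probes were called coding where the files give an mRNA accession (NM or XM) and lncRNA where they give a non-coding RefSeq accession (XR or NR), an ultraconserved element or an identifier starting with MR; other probes stayed unclassed. Accessions were matched without versions to a table of the GRCr8 assembly, used for names only, and 14274 of 15323 coding probes received a symbol. No coordinates are given because no genome of the array design's build was used here. A gene is represented by its probe of highest mean signal, and no gene had probes past the threshold in opposite directions. Of 32 gene lists fixed before the data were examined, 31 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. Members are counted from the adjusted p over all probes and from an adjustment over the list alone. With replicates 2 and 3 counted as 1 array, only numbers 1 and 2 were left to pair.

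Genes named in the report follow a rule fixed before the data were examined, apart from the members the report says were picked later and from a few genes that are not reported here. It took the 10 coding genes with the largest fitted rise and the 10 with the largest fitted fall among those past the threshold whose H/R scans all lay on one side of the control scans, 4 lncRNA probes each way by the same rule, up to 4 members per list with the smallest adjusted p, and 18 genes fixed by name. Alternatives changed the scaling (quantile, median), the background correction (normexp with an offset of 50), the filter on dim probes, the variance prior, the array weights, the test, the threshold, the replicate or scan block, the source of the values and the replicates included. Normexp was run on the median signal and median background of each spot; a mean signal was not used here. A fit that leaves out array 1 or 2 of a group leaves 1 array there, assumed to vary like those of the other group.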

Results

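Messenger RNAs and long non-coding RNAs (lncRNAs) were measured on 1-colour Agilent arrays in H9c2 cells, a myoblast line from embryonic rat heart that is widely used as a cell culture model of cardiac muscle. The series held 3 samples of control cells kept at normal oxygen and 3 samples of cells put through hypoxia/reoxygenation (H/R). For H/R, cells in medium lacking serum and glucose spent 1 h in a gas mixture of 1% oxygen, 5% carbon dioxide and 94% nitrogen, followed by 3 h back at normal oxygen. Culture before treatment was in medium with 10% serum and 4500 mg/L glucose, and the labels do not say which medium the control cells were in during the experiment. The question of the design was which mRNAs and lncRNAs change in level after H/R. Between 58.4% and 71.1% of the 42136 non-control spots were well above background on each array, and 0 spots were saturated. The number of arrays limits the precision of every value.

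The labels describe 3 independent experiments per group, but in each group the files of replicates 2 and 3 carry the same slide position and differ in scan. These 2 files shared 36 spots flagged for uneven local background in the control group and 36 in the H/R group, against at most 1 in the 13 other pairs of files. The deviations of single spots from their probe's mean correlated across spots at r = 0.945 in both pairs and at 0.546 to 0.640 in the other pairs. Spots differed by a median of 0.0229 (control) and 0.022 (H/R) on the log2 scale, against 0.123 to 0.152 for the other pairs within a group, so the difference was less than the noise between arrays. Replicates 2 and 3 were therefore averaged and counted as 1 array, which leaves n = 2 arrays per group. The labels tie no file to a culture of its own, so the p-values of single probes below measure only the spread between these arrays, which may be technical. Those of camera at a preset correlation compare a list's genes with the other genes. Those of Fisher's exact test compare counts of probes. Neither measures the spread between arrays, so their small values are not evidence from more arrays. For tests of single probes limma draws each probe's spread towards that of all probes, with 2 residual and 2.86 prior degrees of freedom. The SEs are moderated in this way too, so a gene with widely differing arrays gets a smaller SE than its own arrays give.

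**Figure D1:**
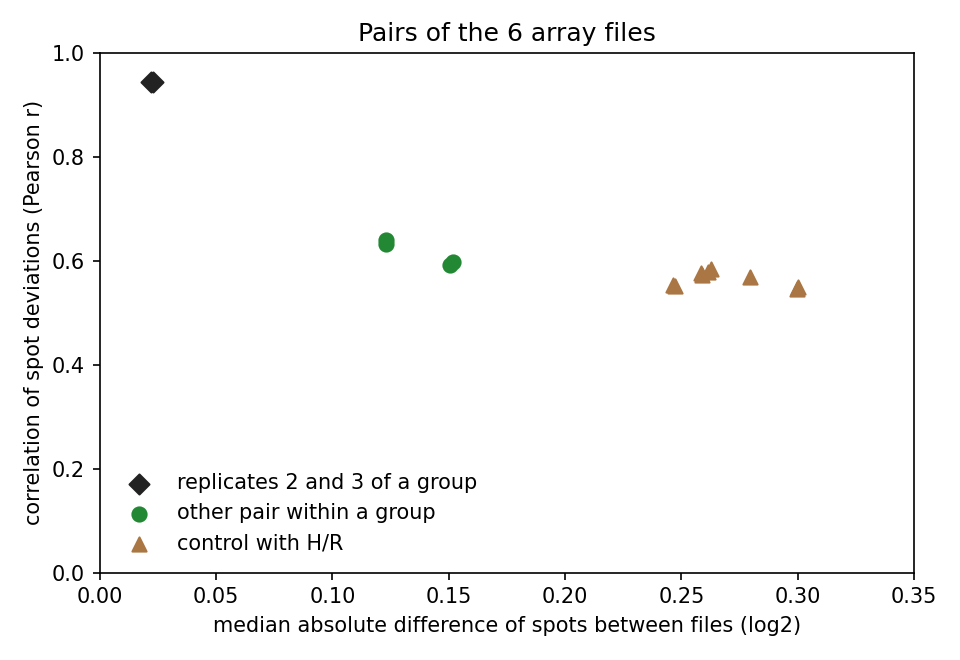
Each point is a pair of the 6 array files, with the median absolute log2 difference between their spots on the horizontal axis and the Pearson correlation, across spots, of the spots' deviations from their probe mean on the vertical axis. Replicates 2 and 3 of each group lie at r = 0.945 and a difference of 0.022 to 0.0229, apart from other pairs within a group (0.123 to 0.152) and pairs across groups (at least 0.2465).

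By camera at a preset correlation, the gene lists of NF-kB targets and cytokines, interferon response and cholesterol synthesis were higher in H/R, and those of growth factor feedback, immediate-early genes and DNA replication were lower. With a correlation estimated from the data, a test that rests on 2 residual degrees of freedom and has little power, 0 lists were called. The chemokine gene Ccl2, which encodes a monocyte attractant, rose 57.0-fold, and Dusp6, which encodes a phosphatase that switches off the kinase ERK, fell to 0.0366 of its control signal (0.0242 without H/R array 1 and 0.0554 without both scans of H/R array 2). Of 15899 probes tested, 3769 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 2358 of them higher and 1411 lower in H/R. Among the changed probes 896 differed at least 2-fold, 609 higher and 287 lower. At gene level, 1618 of 10001 protein-coding genes rose and 962 fell. The first principal component held 80.7% of the variance and separated the groups. When arrays were scaled to their median instead of their 75th percentile, 3819 probes changed but with 1566 higher and 2253 lower, so the excess of rises depended on the scaling. That choice moved the median change of all probes from 0.07 to -0.06 on the log2 scale, and changes are given relative to the 75th percentile throughout. After another background correction (normexp), which moved the median to 0.33, 0 probes passed, with 2044 at an unadjusted p under 0.05 in limma. An ordinary two-sample test of each probe also passed 0 probes after adjustment, with 4575 at an unadjusted p under 0.05. Without the filter on dim probes 594 changed, and without H/R replicate 1 or control replicate 1, each of which leaves 1 array in its group, 1091 and 2040 changed.

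The 10 protein-coding genes with the largest fitted rises are named here. For 4 of them, not well above background in any control scan, the size of the rise is uncertain, so they cannot be ranked against genes measured in both groups. Ccl2 rose by 5.83 ± 0.11 on the log2 scale (moderated SE, here and below, n = 2 arrays per group, limma adjusted p = 0.000437). Ccl7, another monocyte-attracting chemokine, rose by 5.21 ± 0.09 (37.0-fold, adjusted p = 0.000437). Cx3cl1, which encodes fractalkine, was not well above background in any control scan and rose a fitted 51.2-fold (adjusted p = 0.00155). Where a fold is given as at least a value, the mean of the brighter group was compared with a limit for the dim group. That limit was, on each array, the higher of the probe's own signal and the dimmest signal scored well above background. Bounds of this kind leave out the spread between arrays. For Cx3cl1 the probe's own signals were the higher, so 51.2 is the fitted fold and not a bound. Of the interferon-induced genes, Ifit1 rose 13.4-fold and Rsad2, which encodes the antiviral protein viperin, rose at least 7.53-fold. Ifit3 rose 19.9-fold (12.7-fold without control array 1 and 31.0-fold without both scans of control array 2) but was well above background in only 1 of 3 control scans. The others named by this rule were the adaptor gene Stap2 (at least 8.66-fold), Lefty1, which encodes an antagonist of Nodal signalling (at least 4.96-fold), Olfml2a (12.2-fold) and Ckmt1, which encodes a mitochondrial creatine kinase (12.1-fold). Their adjusted p lay between 0.000986 and 0.00580.

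Of the genes with the largest fitted falls, Dusp6 fell by 4.77 ± 0.45 on the log2 scale (adjusted p = 0.00514); its change was -5.37 without H/R array 1 and -4.18 without both scans of H/R array 2. Chrdl2, which encodes a chordin-like antagonist of bone morphogenetic proteins, fell by 3.73 ± 0.11 (adjusted p = 0.00126). Vgf, which encodes a secreted neuropeptide precursor, fell by 3.11 ± 0.14 (adjusted p = 0.00182), and Areg, which encodes the EGF receptor ligand amphiregulin, by 2.63 ± 0.10 (adjusted p = 0.00157). Another 5 were dim in H/R. Klra1, Bpifb1 and the kinase gene Btk were not well above background in any H/R scan, with control signals at least 4.89-fold, 4.94-fold and 5.25-fold higher, so their rank is not supported. Acvr1, which encodes an activin type I receptor, fell by 3.05 ± 0.52 with 2 of 3 H/R scans well above background (-2.40 without control array 1 and -3.71 without both scans of control array 2), and Bicdl2 by 2.94 ± 0.15 with 1 of 3. After normexp correction 118 of the 129 named genes past the threshold kept their direction and none passed. The named genes whose sign turned there were Klra1, Bpifb1, Btk, Acvr1, Bicdl2, Hk2, Ndufa4, Fos, Egr1 and the lncRNAs MRAK035284 and MRAK020214.

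**Figure D2:**
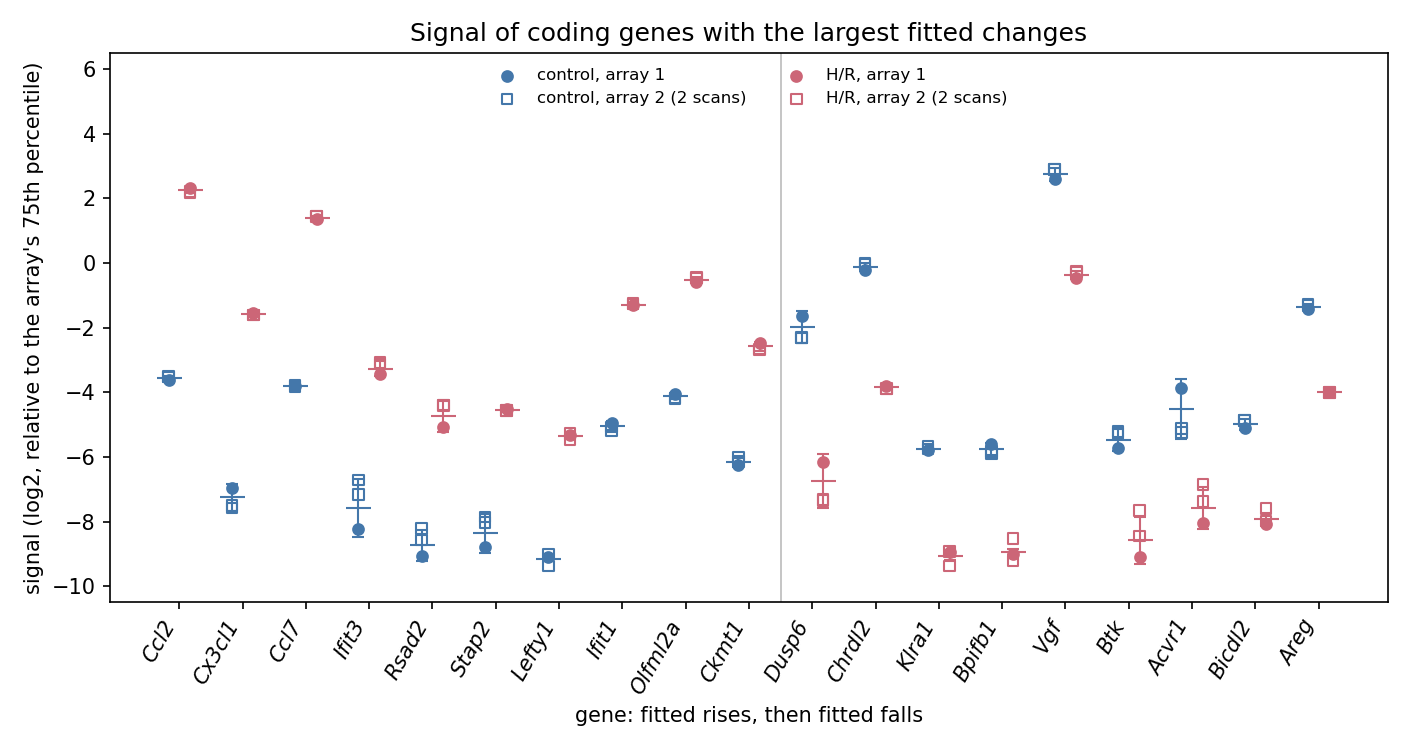
Signal of the protein-coding genes named above for the largest fitted rises (left) and falls (right), on a log2 scale relative to each array's 75th percentile. Filled circles are array 1 and open squares the 2 scans of array 2, and dashes with bars give the mean and SD of the 2 arrays. For each gene every H/R scan lies on one side of every control scan, as the choice of these genes required, from Ccl2 (rose by 5.83) to Dusp6 (fell by 4.77).

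Of 31 gene lists fixed before the data were examined and tested with camera at a preset correlation, 10 were called at an adjusted p under 0.05, 3 of them upward. None was called when the correlation between genes was estimated from the data, and that p is given beside each call. That test rests on 2 residual degrees of freedom and has little power. It therefore does not show that correlation between genes removed the calls. For growth factor feedback and for NF-kB targets and cytokines the estimates were -0.043 and -0.015, below the preset. Their unadjusted camera p still went from 1.37e-09 to 0.0227 and from 6.1e-06 to 0.0378. In the other called lists the estimates lay above the preset. In the list of NF-kB targets and cytokines, 14 of 23 genes tested rose and 1 fell, with a median change of 0.95 (camera adjusted p = 2.7e-05; adjusted p = 0.407 with an estimated correlation). Adjusted over the list alone, 15 rose and 1 fell. Of the 29 members on the array, Il1a, Il1b, Il11, Ccl5, Ccl20 and Lif were too dim to be tested. Besides Ccl2, Ccl7 and Cx3cl1, the neutrophil chemokine gene Cxcl1 rose 10.3-fold (adjusted p = 0.00126). The member that fell was Csf3, which encodes granulocyte colony-stimulating factor, by 0.70 ± 0.14 (adjusted p = 0.0280). Csf3 and the other single members named below because 5 or fewer genes of a list moved that way were picked after their values were seen. In the interferon-response list 16 of 26 genes rose and 0 fell, with a median of 0.92 (camera adjusted p = 2.78e-08; adjusted p = 0.468 with an estimated correlation), and 20 rose when adjusted over the list alone. The ubiquitin-like modifier Isg15 rose 7.15-fold, Oasl 5.13-fold and Ifi44 3.397-fold (adjusted p at most 0.00183). Of 12 macrophage and leukocyte markers tested in the same arrays, 1 rose and 0 fell, with a median of 0.15 (camera adjusted p = 0.189), and 1 rose adjusted over the list alone. The one that rose was Cd74, the invariant chain of class II antigen presentation (2.87-fold, adjusted p = 0.00743, well above background in 2 of 3 control scans). Fcer1g, Csf1r and Aif1 differed by 0.33, 0.40 and 0.24 on the log2 scale and did not pass, and Ptprc, Adgre1, Itgam and Mrc1 were not tested because too few scans were well above background.

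Genes of cholesterol synthesis and uptake rose almost throughout their list. Of 22 tested, 21 rose and 0 fell, with a median change of 1.23 (camera adjusted p = 5.64e-12; adjusted p = 0.468 with an estimated correlation), and 22 rose when adjusted over the list alone. Dhcr7, which encodes the enzyme of the last step to cholesterol, rose by 2.45 ± 0.11, and Hmgcs1, which encodes a synthase early in the mevalonate pathway, by 2.00 ± 0.09 (adjusted p = 0.00182 for both). The squalene synthase gene Fdft1 rose 3.59-fold and the sterol reductase gene Tm7sf2 3.32-fold (adjusted p = 0.00205 for both).

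Genes that growth factor and serum signalling induce fell. In the list of growth factor feedback genes 1 of 17 rose and 13 fell, with a median of -1.26 (camera adjusted p = 1.42e-08; adjusted p = 0.407 with an estimated correlation), and 1 rose and 14 fell adjusted over the list alone. Besides Dusp6, the ERK pathway inhibitor Spry4 fell by 1.74 ± 0.09, the phosphatase gene Dusp5 by 1.63 ± 0.11, the transcription factor gene Etv5 by 1.59 ± 0.09 and Phlda1 by 1.56 ± 0.10 (adjusted p at most 0.00269). The member that rose was the ephrin receptor gene Epha4, by 0.44 on the log2 scale. Immediate-early genes shared 8 tested members with that list. Of 34 tested, 5 rose and 19 fell, with a median of -0.67 (camera adjusted p = 5.88e-06; adjusted p = 0.407 with an estimated correlation), and 6 rose and 21 fell adjusted over the list alone. The orphan nuclear receptor gene Nr4a1 fell by 2.15 ± 0.10, Egr2 by 2.15 ± 0.11 and Id1 by 1.90 ± 0.09 (adjusted p at most 0.00183). Fos fell by 1.53 ± 0.24 (adjusted p = 0.0154) and Egr1 by 1.35 ± 0.29 (adjusted p = 0.0320). The 5 members that rose were Klf4, Atf3, Rgs2, Klf6 and Btg1, of which Atf3, a stress-induced transcription factor gene, rose 1.57-fold (adjusted p = 0.0119). In the list of MRTF/SRF and YAP targets, which respond to actin and cell shape, 0 of 27 rose and 7 fell, with a median of -0.14 (camera adjusted p = 0.00394; adjusted p = 0.468 with an estimated correlation), and the same counts held adjusted over the list alone. Its falls included those of Areg, of Hbegf, which encodes an EGF receptor ligand (fell by 1.26 ± 0.15), and of Srf itself (fell by 0.93 ± 0.09).

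Genes of DNA replication fell together. Of 32 tested, 0 rose and 22 fell, with a median of -0.61 (camera adjusted p = 6.58e-13; adjusted p = 0.468 with an estimated correlation), and 26 fell adjusted over the list alone. The replication origin genes Orc1, Cdc6 and Cdc45 fell by 1.44 ± 0.10, 1.35 ± 0.11 and 1.16 ± 0.11, and Ccne2, which encodes cyclin E2, by 1.44 ± 0.14 (adjusted p at most 0.00519). In the mitosis list 0 of 27 rose and 3 fell, with a median of -0.12 (camera adjusted p = 0.0423; adjusted p = 0.576 with an estimated correlation), and 1 fell adjusted over the list alone. These were the kinase gene Aurkb (fell by 0.64), the cyclin gene Ccna2 (fell by 0.47) and Pbk (fell by 0.40), and the list's call was lost under several other settings, with adjusted p up to 0.0969. Of 29 ribosome biogenesis genes 0 rose and 8 fell, with a median of -0.30 (camera adjusted p = 7.26e-06; adjusted p = 0.468 with an estimated correlation), and 13 fell adjusted over the list alone. Rrs1 fell by 1.03 ± 0.10 and Fbl, which encodes the nucleolar protein fibrillarin, by 0.59 ± 0.10, with Utp18 and Utp4 down by 0.61 and 0.46. Replication-dependent histone genes did not follow, with 3 of 11 up and 0 down, adjusted over all genes or over the list alone, and a median of 0.21 (camera adjusted p = 0.108). Hist1h2bq rose 2.03-fold, and Hist1h4b and Hist3h2ba, not well above background in any control scan, rose at least 2.01-fold and 2.28-fold, although probes of near-identical histone genes can bind each other's RNA.

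Targets of hypoxia-inducible factor (HIF) moved both ways and the list was not called. Of 28 tested, 11 rose and 3 fell, also adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.0946). Ndrg1 rose by 2.68 ± 0.09 (adjusted p = 0.00155), Ddit4, which encodes the mTORC1 inhibitor REDD1, by 1.63 ± 0.10 (3.09-fold, adjusted p = 0.00225), and the carbonic anhydrase gene Car9 2.82-fold (adjusted p = 0.00440). Pfkfb4, not well above background in any control scan, rose a fitted 1.85-fold. Vegfa, which encodes the main angiogenic growth factor, rose 1.52-fold (adjusted p = 0.0173), with all 5 of its probes between 0.60 and 0.67 on the log2 scale. The 3 that fell were Higd1a, Hk2 and Stc2. The glucose transporter gene Slc2a1 differed by -0.16 ± 0.10 and the lactate dehydrogenase gene Ldha by 0.15 ± 0.11, and neither passed (adjusted p = 0.272 and 0.359). Of 17 glycolysis genes 0 rose and 2 fell, also over the list alone (camera adjusted p = 0.598, direction down, with a median of 0.07 and a mean of -0.03). The hexokinase gene Hk2 fell by 0.73 ± 0.11 and Pfkp, which encodes a phosphofructokinase, by 0.65 ± 0.09, while Tpi1 and Pfkm did not pass (0.32 and 0.24). Txnip, which encodes a glucose-regulated inhibitor of glucose uptake, differed by -0.35 ± 0.10 and did not pass (adjusted p = 0.0681).

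Stress-response lists were mixed. Of 28 integrated stress response (ATF4) targets 7 rose and 3 fell, 8 and 3 over the list alone, with a median of 0.19 (camera adjusted p = 0.553). Gdf15, which encodes a stress cytokine, rose at least 3.28-fold from below background, Nupr1 2.24-fold, Fgf21 1.83-fold and Ddit3, which encodes the factor CHOP, 2.04-fold (adjusted p = 0.0402). Endoplasmic reticulum (ER) chaperone genes gave a downward call, with 1 of 20 up, 3 down and a median of -0.22 (camera adjusted p = 0.0185; adjusted p = 0.576 with an estimated correlation), and 1 up and 4 down over the list alone. Atf6, which encodes an ER stress sensor, fell by 0.68, Creld2 by 0.56 and Hyou1 by 0.45, while Herpud1, which acts in ER-associated degradation, rose 1.48-fold, and the call was lost in 2 other settings (adjusted p up to 0.0581). Among 27 NRF2 targets 6 rose and 6 fell, 8 and 6 over the list alone, with a median of 0.09 (camera adjusted p = 0.775). The epoxide hydrolase gene Ephx1 rose 3.02-fold, Osgin1 2.10-fold and the glutathione transferase gene Gsta3 2.09-fold, while Hmox1, which encodes the haem-degrading enzyme HO-1, fell by 0.78 ± 0.09 (adjusted p = 0.00790). Of 19 antioxidant enzyme genes 4 rose and 1 fell, also over the list alone, with a median of 0.18 (camera adjusted p = 0.352). The metallothionein gene Mt2A rose 3.32-fold, Sod3 1.69-fold and the mitochondrial superoxide dismutase gene Sod2 1.45-fold, and Txnrd2 fell by 0.86. Of 16 heat-shock genes 0 rose and 2 fell, 0 over the list alone (camera adjusted p = 0.620, direction down, with a median of 0.00 and a mean of 0.01). Hspa4 fell by 0.39 and Dnajb4 by 0.51, while Hspa8 and Bag3 did not pass (0.37 and 0.31). Of 17 genes of nuclear export and splicing 1 rose and 1 fell, 1 and 0 over the list alone (camera adjusted p = 0.553, direction down, with a median of -0.06 and a mean of 0.02). Srsf3 rose 1.72-fold and Srsf2 fell by 0.39, while Cirbp and Srsf7 did not pass (0.55 and -0.41).

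Muscle genes also split. Of 22 cardiac muscle markers 4 rose and 2 fell, also over the list alone (camera adjusted p = 0.718, direction down, with a median of 0.06 and a mean of 0.07). The cardiac troponin T gene Tnnt2 rose 2.18-fold and Myh6, which encodes the alpha myosin heavy chain, 1.98-fold, while Nppb, which encodes the natriuretic peptide BNP, fell by 1.41 ± 0.11 (adjusted p at most 0.00527). Nppa, which encodes the natriuretic peptide ANP, did not pass (-0.07 ± 0.31, adjusted p = 0.886). Of 18 skeletal myoblast markers 8 rose and 1 fell, also over the list alone, with a median of 0.45 (camera adjusted p = 0.189). The fast troponin T gene Tnnt3 rose 2.06-fold, the embryonic myosin gene Myh3 1.72-fold and Tnni2 1.54-fold, and the myogenic factor gene Myod1 fell by 1.48 ± 0.18 (adjusted p = 0.00814). Myog, which encodes myogenin, did not pass (0.06 ± 0.10, adjusted p = 0.691). Of 12 fibroblast markers 3 rose and 0 fell, also over the list alone, with a median of 0.28 (camera adjusted p = 0.0625). These were the proteoglycan genes Lum (4.41-fold) and Dcn (1.66-fold) and the PDGF receptor gene Pdgfrb (1.42-fold), while Vim did not pass (0.40). Of 9 endothelial markers on the array, Pecam1, Cdh5, Erg and Sox17 were too dim to be tested. Among the 5 tested, of which 3 were well above background in every scan, 2 rose and 0 fell, 4 and 1 over the list alone. Their median was 1.11 (camera adjusted p = 0.203). Tek, an angiopoietin receptor gene, rose 2.16-fold and Esam 2.59-fold, while Flt1 and Emcn did not pass (-0.59 and 0.32). One label names brain cortex of mice as the RNA source, against the rat heart line named in the others, so markers of brain cells were also looked at. Of 22 on the array, 13 were too dim to be tested, among them the neuronal genes Rbfox3, Slc17a7, Gad1 and Camk2a. Of the 9 tested 3 rose and 0 fell, 5 and 0 over the list alone, with a median of 0.49 (camera adjusted p = 0.0625). The glutamate transporter gene Slc1a3 rose 3.58-fold, while Olig1 did not pass (0.48). S100b, not well above background in any control scan, rose a fitted 1.61-fold.

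The remaining lists were not called. Of 32 autophagy and lysosome genes 6 rose and 0 fell, also over the list alone, with a median of 0.24 (camera adjusted p = 0.0625), among them the autophagy kinase gene Ulk1 (1.503-fold), the lysosomal galactosidase gene Gla (1.54-fold), Atg4c (1.38-fold) and Atg7 (1.54-fold). Of 19 FoxO targets 7 rose and 1 fell, 9 and 2 over the list alone, with a median of 0.30 (camera adjusted p = 0.0645). Klf15 rose 3.32-fold, Bcl2l11, which encodes the pro-apoptotic protein BIM, 2.23-fold, Ypel3 1.97-fold and Sesn3 1.65-fold. Of 27 genes of the BCL2 family and caspases 9 rose and 1 fell, also over the list alone, with a median of 0.07 (camera adjusted p = 0.352). Besides Bcl2l11 the pro-apoptotic gene Bmf rose 2.32-fold and the inflammatory caspase genes Casp4 and Casp12 2.12-fold and 1.64-fold. Of 19 p53 targets 4 rose and 1 fell, 5 and 1 over the list alone, with a median of 0.25 (camera adjusted p = 0.108). The death receptor gene Fas rose 3.15-fold, Tp53inp1 1.75-fold and Gadd45a 1.77-fold, and the kinase gene Plk3 fell by 0.95. Of 14 circadian clock genes 3 rose and 2 fell, also over the list alone, with a median of 0.13 (camera adjusted p = 0.620). The clock output genes Dbp, Ciart and Tef rose 3.30-fold, 2.63-fold and 2.14-fold, and Nfil3, which encodes a repressor of the same promoter element as DBP binds, fell by 0.84. Of 21 extracellular matrix genes 6 rose and 1 fell, also over the list alone, with a median of 0.27 (camera adjusted p = 0.189). Besides Lum, Timp3 rose 2.05-fold and Mmp2 2.05-fold, and the membrane protease gene Mmp14 fell by 1.67 ± 0.12. Of 43 nuclear genes of oxidative phosphorylation 0 rose and 1 fell, 0 over the list alone, with a median of 0.11 (camera adjusted p = 0.827). That gene was Ndufa4 (fell by 0.62), while Ndufb10, Ndufs4 and Atp5f1c did not pass (0.39, 0.31 and 0.31).

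Fewer lncRNA than protein-coding probes changed. Of 3544 lncRNA probes tested 660 changed (18.6%), 387 higher and 273 lower in H/R, against 2832 of 11026 coding probes (25.7%), 1790 higher and 1042 lower (odds ratio for coding against lncRNA 1.51, two-sided Fisher's exact test p = 2.71e-18; probes are not independent replicates). The share changed was also lower for lncRNA in each of 4 bins of signal, from 15.3% against 25.1% in the dimmest to 12.98% against 17.399% in the brightest. Among changed probes 58.6% of lncRNA and 63.2% of coding probes were higher in H/R (Fisher's exact test p = 0.0322). Under median scaling these shares were 34.6% and 42.5%, and the difference did not pass Fisher's exact test with the first scan only (p = 0.108), without control replicate 3 (p = 0.0744), without the filter on dim probes (p = 0.126) or in the fits of 6 scans as separate samples (p of 0.470 to 0.932), so it depends on the setting. Of lncRNA probes named by their fitted rise, MRAK134679, MRNR_003508, XR_006875 and XR_006095 were not well above background in any control scan and rose at least 6.18-fold, 5.97-fold, 2.43-fold and 2.58-fold (adjusted p at most 0.00528), bounds that do not rank them against other lncRNA probes. The 4 largest fitted falls were those of MRAK159688, by 2.41 ± 0.19, MRAK035284, by 2.16 ± 0.11, MRAK020214, by 2.10 ± 0.23, and MRAK144357, by 1.88 ± 0.14 (adjusted p at most 0.00657). Of lncRNAs with a known name, the imprinted H19 and the snoRNA host gene Gas5 did not pass (0.09 ± 0.17, adjusted p = 0.712, and 0.00 ± 0.14, adjusted p = 0.988). Malat1, Neat1 and Meg3 were paired with no probe and are not analysed here, and the list of known lncRNAs had 4 tested members, too few for a set test.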

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

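Alternatives added after seeing the data were those treating the 6 scans as separate samples without a block or with a replicate block, using the first scan only, leaving out both scans of an array, and quantile normalization after normexp correction. Of the 10 called gene lists, 8 were called in all 23 fits compared, and mitosis was called in 16 (adjusted p up to 0.0969) and ER chaperones in 21 (up to 0.0581), with every one of the 10 in the direction reported. With a correlation estimated from the data, a test of little power on 2 residual degrees of freedom, 0 lists were called. With fry, which does not compare a list with other genes, 17 were. The count of changed probes stayed within 1.5 times the reported 3769 under quantile normalization (3694, of which 3280 were shared in the same direction), median scaling (3819, 2961 shared), the authors' normalized values (3178), the stricter filter (3790), a trended robust prior (4661), array weights (3813), the first scan only (3748, 3648 shared) and without both scans of control array 2 (2702). The share of changed probes higher in H/R, reported as 62.6%, was 53.8% with quantile normalization, 41.0% with median scaling, 59.8% with probes above background in all 6 scans, 53.2% with the authors' values, 58.8% with the trended robust prior and 52.8% with normexp then quantile normalization, and the cause was not tested. Normexp correction left 0 changed probes, 0 coding and 0 lncRNA, with 2044 at an unadjusted p under 0.05 in limma. The median difference between the 2 H/R arrays grew from 0.12 to 0.40 on the log2 scale there, and quantile normalization after normexp gave 4313 changed probes, 3053 of them shared, so the loss went with the 75th-percentile scaling of normexp values. The ordinary two-sample test per probe, with 2 residual degrees of freedom, passed 0 probes, 0 coding and 0 lncRNA, with 4575 at an unadjusted p under 0.05.

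Without a filter on dim probes 594 probes changed, 469 coding and 91 lncRNA, 72.7% of them higher, over 24578 probes tested. With an additional minimum of 2-fold there were 896, 710 coding and 142 lncRNA (68.0% higher), and at an unadjusted p with 2-fold 947, 749 coding and 151 lncRNA (67.9% higher). Treating 6 scans as separate samples gave 8309 probes, 5994 coding and 1634 lncRNA (58.4% higher), with scan as a block 7423, 5382 coding and 1442 lncRNA (58.8% higher), and with a replicate block 8426, 6032 coding and 1706 lncRNA (58.1% higher). These 3 fits count scans of 1 array as samples. For the fit without a block this made most calls false in the simulation, and the 2 with a block were not simulated. Within the first scan the medians of the NF-kB, interferon, cholesterol, growth factor feedback and DNA replication lists were 0.93, 0.92, 1.21, -1.26 and -0.60, and with scan as a block 0.96, 0.93, 1.20, -1.21 and -0.62. The second scan holds 1 file per group and gives no test. With the replicate block on the averaged arrays 3886 probes changed, 60.9% higher, and the mitosis list was lost (adjusted p = 0.0510). Same-numbered arrays deviated from their group means with r = 0.153 across probes, a value that is the same for both pairs with 2 arrays per group, so the numbers are not taken to pair the samples. Leaving out only replicate 2 or only replicate 3 drops 1 of 2 files counted as 1 array, and that array stays in the fit. Ranges over the replicates left out therefore understate how far the results depend on single arrays. Leaving out each replicate in turn gave 1091 to 3778 changed probes, 834 to 2832 coding, 193 to 663 lncRNA, shares higher of 62.4% to 67.6% and 10 to 12 called lists. The lowest count came without H/R replicate 1, whose removal leaves 1 array in that group, and without control replicate 1 there were 2040. Without both scans of H/R array 2 there were 1008, 780 coding and 168 lncRNA.

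Of the 129 named genes past the threshold, at least 122 still passed under quantile normalization, median scaling, the authors' values, the replicate block and normexp then quantile normalization, with the same direction, and 68 without the filter, 88 without H/R replicate 1, 83 without both scans of H/R array 2 and 106 without control replicate 1. Under normexp 0 passed, and log2 changes turned to 0.69 (Klra1), 0.67 (Bpifb1), 0.59 (Btk), 0.21 (Acvr1), 0.39 (Bicdl2), 0.44 (Flt1), 0.46 (Hk2), 0.84 (Ndufa4), 0.41 (Fos), 0.56 (Egr1), 0.36 (Nppa), -0.0059 (H19), -0.13 (Gas5), 0.24 (MRAK035284) and 0.39 (MRAK020214), against a median of all probes of 0.33. Klra1, Bpifb1 and Btk were not well above background in any H/R scan, so the sizes fitted for them are not supported. Sign changes elsewhere were in genes that did not pass, and their cause was not tested. Median scaling gave Myog -0.066, H19 -0.035 and Gas5 -0.12. Normexp then quantile normalization gave Aif1 -0.061, Myog -0.040, H19 -0.0034 and Gas5 -0.027. The fits of 6 scans as separate samples, with and without the scan or replicate block, gave H19 -0.0101. Leaving out each replicate in turn, Nppa ranged from -0.398 (without control replicate 1) to 0.264 (without H/R replicate 1), H19 from -0.0953 (without H/R replicate 1; -0.0280 without control replicate 1) to 0.096 and Gas5 from -0.111 (without control replicate 1) to 0.119, without both scans of control array 2 Nppa was 0.26, and without both scans of H/R array 2 Myog was -0.0078 and Gas5 -0.11. Among lists, only some that were not called changed direction. For oxidative phosphorylation the median with the test turned was -0.0157 under median scaling, 0.0254 under normexp, 0.0637 in the 6-scan fits with and without the scan block, 0.0111 without control replicate 1 and 0.0403 without H/R replicate 1, with a range of 0.0111 to 0.112 over the replicates left out. Under normexp the antioxidant, cardiac muscle, ATF4 and NRF2 lists turned (medians 0.0386, 0.20, 0.15 and 0.0279). Without H/R replicate 1 the cardiac and NRF2 lists turned (0.147 and 0.0354, within ranges of 0.0552 to 0.147 and 0.0185 to 0.0944 over the replicates left out), with 6 scans as separate samples the NRF2 list (0.0735), without both scans of control array 2 the heat-shock list (0.0400) and without both scans of H/R array 2 the glycolysis list (0.19).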

Other observations

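All tests of this part were chosen, or their expected outcomes written, after the results were seen. Gene families were formed from the shared start of gene symbols, and 111 families had at least 10 tested coding genes. By camera at the preset correlation 5 were called, and with an estimated correlation 0 were (adjusted p = 0.947 for each). Nucleoporin genes (Nup), which build the nuclear pore, had 0 of 16 up and 9 down, with a median of -0.43 (camera adjusted p = 0.000327), led by Nup54 (fell by 0.70 ± 0.10, SE) and Nup160 (fell by 1.09 ± 0.18). Genes of mitochondrial inner-membrane import (Timm) had 0 of 11 up and 3 down, with a median of -0.39 (adjusted p = 0.0202), and RNA polymerase subunit genes (Polr), 3 of them also on the ribosome biogenesis list, 0 of 27 up and 5 down, with a median of -0.16 (adjusted p = 0.0202). Under the other scalings the medians stayed between -0.56 and -0.33, -0.52 and -0.27, and -0.29 and -0.14. Cilia and flagella associated genes (Cfap) had 7 of 18 up and 0 down, with a median of 0.32 (adjusted p = 0.0202; 0.19 to 0.67 under the other scalings), led by Cfap52 at 5.37-fold. Clustered protocadherin-beta genes (Pcdhb), which code for neural cell adhesion proteins, had 7 of 11 up and 0 down, with a median of 0.70 (adjusted p = 0.0117; 0.15 to 1.04 under the other scalings), and probes of such similar genes can bind each other's RNA.

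Replicates 2 and 3 of each group were nearly identical. If they were 1 RNA sample on different arrays, single spots should deviate no more alike than on other arrays, but their deviations correlated at 0.945 against at most 0.640 in other pairs. The 36 shared background faults per pair, against at most 1 elsewhere, are what 1 array scanned 2 times would give, a candidate explanation that the slide position, the same in both files, also meets. Whether the labels of these files or the choice of files is at fault was not tested.

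The rise of cytokine and interferon genes could come from leukocyte RNA, from scaling, or from the treatment. The median change of 12 leukocyte markers was 0.15, with a bootstrap upper limit of 0.32 over genes, against 0.95 for 49 inflammatory genes, and the markers' median stayed below that of the inflammatory genes beyond the bootstrap limit under 4 of 5 other scalings. Under normexp correction the medians were 0.90 and 1.04, with an upper limit of their difference of 0.20, so leukocyte RNA stays open; Lyz2, a macrophage transcript, differed by 0.14 ± 0.12 under the reported scaling, and 4 more markers were well above background in too few scans to be tested. Scaling is argued against, because the lower of the medians of the 2 lists was 0.44 or more under 5 other scalings. The treatment, as a hypothesis, also stays open, and its low oxygen, reoxygenation and change of medium were not separated.

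The fall of growth factor feedback genes may follow from the medium without serum or from low oxygen and reoxygenation. The list's median was -1.26, and -0.77 was the value closest to 0 under 5 other scalings, which argues against scaling. The list of HIF targets, which low oxygen raises, had a median of 0.21. The H/R cells were in medium lacking serum and glucose, the labels do not give the medium of the controls, and no arm changes oxygen or medium alone, so these 2 explanations cannot be told apart.

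The count of changed probes was compared with other splits of the samples. Of the 10 splits of the 6 scans into 3 and 3, 1, the real one, gave as many as the real 8309, and the highest of the others gave 0. Of the 3 splits of the 4 arrays 1, again the real one, gave 3769, and the highest other gave 0. Every other split put control and H/R files on both sides, so the group difference added to its residual spread and made calls unlikely. Both designs also have too few splits for a share under 0.05, so these counts decide nothing about chance.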
